A study of Mus musculus with 12 samples.

How the data were processed

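The series holds expression profiles of 2 sorted fractions of mouse mammary cells, MaSC-enriched and luminal, from control and ovariectomized FVB/NJ mice. Up to 250 ng of total RNA was labelled and hybridised to Illumina BeadChips, per the labels. The 12 arrays cover 8 RNA samples from 4 mouse pools (2 control, 2 ovx), and 4 of the RNAs were run on a second array. RNA from different pools was taken as the biological replicate, and arrays of the same RNA were averaged.

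The deposited non-normalized table gives, per the file headers, a summarised bead intensity and a detection p-value for each of 45281 probes on each array. The lowest intensity on each array lay between 80.3 and 100.1 and the array medians between 126.6 and 199.2, so these intensity values are neither background-subtracted nor scaled between arrays. The deposited series table gives normalized values that fit a log2 scale, with array medians of 6.22 to 6.23 and the same rank order as the intensity of the same array. The submitters' processing notes name BeadStudio and limma, without a version or a role. No control probe values were used here.

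The intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function corrected background with negative control parameters inferred from the detection p-values, added an offset of 16, quantile normalized all 12 arrays and took log2. Probes were kept when the mean detection p over a sample's arrays was under 0.05 in at least 2 of the 8 samples, which left 20995 probes (46.4%) for 11292 genes. A gene is represented by its kept probe with the highest mean. The number of probes detected per array, between 12994 and 18903, stands for depth, and the number of samples sets the precision. The lowest log2 signal of a detected probe was 7.29 on the array of control MaSC-enriched replicate 1 and 5.73 to 5.93 on the others, so dim transcripts were harder to detect in that sample.

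Pairs of single arrays correlated at 0.992 to 0.994 for the same RNA, at 0.882 to 0.986 for the same group from other pools and at 0.796 to 0.965 for other groups. A limma model with a mean for each of the 4 groups (4 residual and 3.22 prior degrees of freedom) was fitted to the 8 samples, and moderated two-sided tests were adjusted by Benjamini-Hochberg over all kept probes, with a threshold of 0.05. The 5 comparisons were ovx against control in each fraction, the difference of these effects, and MaSC-enriched against luminal cells in control and in ovx mice. With 2 samples against 2 the smallest exact p is 0.333, so the tests rest on limma's spread shared across probes and groups. A fold written "at least" has each array of the lower group that lies below its detection floor raised to that floor. Log2 changes of genes near the floor are fitted values that depend on the offset. The bounds hold for the main fit, and other settings gave smaller changes for some genes.

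The pool numbers pair the MaSC-enriched and luminal samples. To check the pairing, deviations of samples from their group means were correlated across probes, which gave 0.367 for the control and 0.135 for the ovx pools. Samples that share a replicate number without a pool gave 0.587 for MaSC-enriched and 0.279 for luminal cells, so this check does not single out the pool, and the pairing rests on the labels. The fit with the pool as a fixed block was the alternative for the cell type comparisons and the difference of effects, beside the pool as a random block. Control and ovx samples share a replicate number but no pool.

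The 25 gene lists (451 genes, 356 of them tested) were fixed before the data were examined, as were the comparisons, the main settings and most alternatives. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation and with fry. No list passed with an estimated correlation in any comparison, and fry, a rotation test that asks whether the list itself changed and keeps the correlation between its genes, passed 0 lists in the ovx comparisons, 7 in the cell type comparison in control mice and 9 in that in ovx mice. The genes named in the text follow a rule fixed before the data were examined. It takes up to 10 genes per direction past the threshold for the ovx comparisons and 5 for the difference of effects and the cell type comparison in control mice, where the samples of the groups do not overlap. To these it adds up to 4 members of each list with the smallest p and 12 marker genes; of these Areg and Mki67 had no tested probe. Clone and locus names were counted without being named. The test of 14 further muscle genes was added after muscle genes were seen among the called ones, and the splits of the pools after the correlation of effects was seen.

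The fit and the calls were tested on simulated log2 values built with the moderated spread of each probe, with 67 probes changed by a log2 of 1, 67 by 2 and 66 by 4 in each comparison. At a true log2 change of 4, 97% were called for ovx in MaSC-enriched, 95.5% for ovx in luminal cells, 39.4% for the difference of effects, and 93.9% and 97% for the cell type comparisons. At a change of 2 these were 28.4%, 38.8%, 0%, 20.9% and 31.3%. At a change of 1 the share was 1.49% for ovx in MaSC-enriched cells and 0% in the other comparisons. Between 0 and 9 unchanged probes were called, and no change was called in the wrong direction. The simulated probes were independent, with the same spread in all groups, and the background correction, normalization and filter were not simulated. In the measured data genes correlate, pools are shared and the spread is unequal. The SD of the log2 difference between replicates was 1.17 in control MaSC-enriched and 0.381 in ovx luminal cells. The simulated shares therefore need not hold for the measured data.

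Alternatives were an offset of 50, no background correction, 75th percentile scaling, the deposited normalized table, no filter and a strict filter (detection p under 0.01 on each array of at least 1 group), the first array of each RNA, all 12 arrays with the RNA as a random block (correlation 0.877) with or without the beadchip as a block, each beadchip alone (with 1 sample per luminal group on beadchip 1 and 1 per MaSC-enriched group on beadchip 2), a mean-variance trend, array weights, the groups of a comparison alone, replicate and pool blocks, and each sample left out in turn. Where a beadchip alone or leaving a sample out left 1 in its group, that sample was assumed to vary like the other groups. The fits of all 12 arrays count second arrays of an RNA towards the residual degrees of freedom, so their counts can run high. List tests within each beadchip, the omission of both control replicate 2 samples and the count without muscle genes were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes without a gene symbol (10378 of 45281) were tested but not named.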

Results

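Gene expression was measured in mammary epithelial cells of control and ovariectomized (ovx) female FVB/NJ mice. Ovariectomy removes the ovarian source of oestrogen and progesterone. Per the labels, surgery was done at an age of 8 weeks, glands were taken 4 weeks after it, and each ovx pool combined 6 mice. These fields are empty for the control pools, so a match in age, sham surgery or pool size could not be checked. Cells lacking the blood and endothelial surface markers CD45, CD31 and TER119 were sorted by CD24 and CD29 into a mammary stem cell-enriched fraction (MaSC-enriched, CD29hi CD24+), which also holds the basal and myoepithelial cells, and a luminal fraction (CD29lo CD24+), each at a stated purity over 90%. The 4 groups, control and ovx in each fraction, held 2 RNA samples each, and by the pool numbers in the labels each of the 4 mouse pools gave both fractions. With a second array for 4 of the RNAs, 12 arrays were run on 2 beadchips, and the number of pools limits the precision. Beadchip 1 held all MaSC-enriched samples but only replicate 1 of the luminal groups, and beadchip 2 all luminal samples but only replicate 2 of the MaSC-enriched groups. Between 17705 and 18903 of the 45281 probes were detected on 11 of the arrays, and 12994 (28.7%) on the array of control MaSC-enriched replicate 1. The first principal component, with 55.8% of the variance, parted the fractions. The second, with 21.2%, set both samples of the control replicate 2 pool apart, at 92.5 for MaSC-enriched and 73.9 for luminal cells, while the other 6 samples lay lower, with ovx MaSC-enriched replicate 1 at −51.6.

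The comparison of ovx with control MaSC-enriched cells asks what loss of the ovaries changed in the basal fraction. The milk protein gene Csn2 (beta-casein) fell by 8.46 on the log2 scale (SE 0.641, adjusted p = 0.0113), or at least 296-fold with the detection floor in place of lower signals, from a mean log2 level of 14.08 ± 0.178 (SD, n = 2) to 5.62 ± 0.222 (SD, n = 2). Trim9, a ubiquitin ligase known from neurons, was at least 18.9-fold higher in ovx cells (log2 fold change 5.34, SE 0.297, adjusted p = 0.00617), since no control array detected it. Nrcam, a cell adhesion molecule, rose by 5.18 (SE 0.341, adjusted p = 0.0102; at least 19.5-fold), and a second Nrcam probe rose by 2.79 without passing (adjusted p = 0.0516). Lep, which encodes the adipocyte hormone leptin, was at least 15.7-fold higher (log2 fold change 4.77, SE 0.45, adjusted p = 0.0226). Other genes that rose were Wfikkn2 (at least 9.28-fold, with another probe at −1.12), Frmpd4 (at least 6.62-fold), Lrrn2 (at least 7.04-fold) and Brinp1 (at least 3.39-fold), with adjusted p from 0.0226 to 0.0458. Genes were named only where the 2 ovx samples did not overlap the 2 control samples, so the 8 show the direction in all 4 samples by choice.

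In the limma fit 16 of 20995 probes passed an adjusted p of 0.05 in this comparison, 14 higher and 2 lower in ovx cells, and 1811 had an unadjusted p under 0.05. These probes stood for 10 genes higher and 1 lower, with 5 probes that carry no gene symbol. The split moved to 15 higher and 7 lower with an offset of 50, and to 13 and 6 without background correction. With all 12 arrays, the RNA as a random block and the beadchip as a block, 81 probes passed. That fit counts second arrays of an RNA towards the degrees of freedom, so its larger count is not an effect of the beadchip alone. Within beadchip 1, with fewer samples, none passed. The count changed with each library left out: none passed without ovx MaSC-enriched replicate 2, 7 without ovx MaSC-enriched replicate 1, 2 without any single luminal sample, 76 without control MaSC-enriched replicate 1 and 583 without control MaSC-enriched replicate 2. Without both samples of the control replicate 2 pool, chosen after the data were seen, 410 probes passed, 88 higher and 322 lower, and all 16 were among them. Trim9 lost its call without ovx MaSC-enriched replicate 2, Nrcam without that sample or either ovx luminal sample, and Lep without that sample or any luminal sample. Csn2 lost it without either ovx MaSC-enriched or either control luminal sample, and Wfikkn2, Frmpd4, Lrrn2 and Brinp1 without any sample other than the control MaSC-enriched ones. Without control MaSC-enriched replicate 2, the control group rests on replicate 1 alone, the array with 12994 detected probes and a detection floor of 7.29. The larger counts in these settings therefore do not show that replicate 2 hid true changes.

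**Figure D1:**
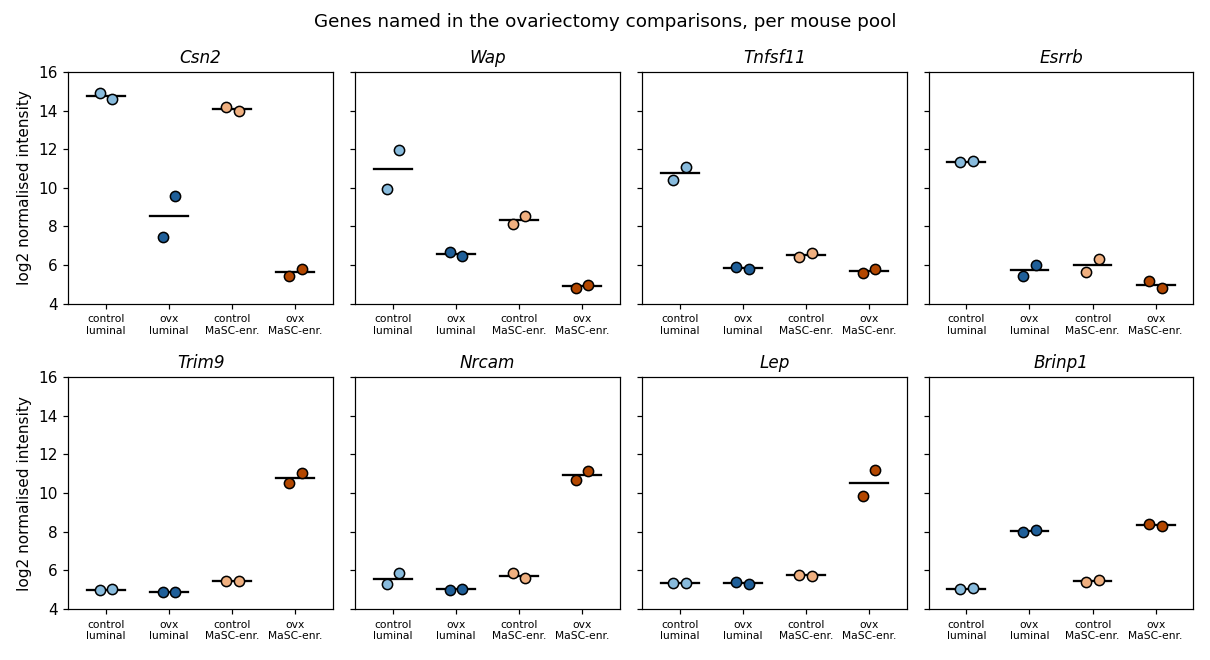
Log2 normalised intensity (vertical axis) of 8 genes in the 4 groups (horizontal axis), with a point for each of the 2 samples per group and a line at the group mean. Csn2 falls from 14.08 to 5.62 in MaSC-enriched cells and from 14.76 to 8.52 in luminal cells, Tnfsf11 and Esrrb are high in control luminal cells, and Trim9, Nrcam and Lep are high in ovx MaSC-enriched cells.

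Among the gene lists, milk protein and secretory genes fell in ovx MaSC-enriched cells (16 tested, median log2 fold change −1.63, camera adjusted p = 5.18e-07; adjusted p = 0.621 with an estimated correlation). Csn2 alone of the 16 passed over all probes, and 6 passed adjusted over the list alone, all lower. Csn1s1 stood at −3.77 (adjusted p = 0.0516), and the whey acidic protein gene Wap was at least 5.66-fold lower without passing (adjusted p = 0.131). The basal and myoepithelial markers rose (24 tested, median 0.49, adjusted p = 0.00493; 0.621 as the p with an estimated correlation). None passed over all probes and 4 passed adjusted over the list alone, all higher. The smooth muscle genes Cnn1 (at least 2.52-fold) and Lmod1 (1.82) were among the members with the smallest p, at adjusted p = 0.121 and 0.153. Adipocyte markers rose (5 tested, median 1.28, adjusted p = 0.00103; 0.483 as the p with an estimated correlation). Lep was the member past the threshold, over all probes and adjusted over the list alone, beside Adipoq (at least 1.75-fold higher) and Car3 (at least 1.63-fold). Pericyte markers rose as well (9 tested, median 0.52, adjusted p = 0.028; 0.621 as the p with an estimated correlation). No member passed over all probes and 1 adjusted over the list alone. The milk and adipocyte calls held without each library in turn and within beadchip 1 (milk −1.64, adipocyte 1.29), but the medians moved. Within beadchip 2, where 1 MaSC-enriched sample stands against 1, the medians were −0.29 and 0.63, which tests neither call. Without control MaSC-enriched replicate 1 the milk median was −0.18, and without control MaSC-enriched replicate 2 −2.48. The adipocyte median was 0.60 without ovx MaSC-enriched replicate 1, 0.85 with an offset of 50 and 0.33 without the filter on dim probes. Without control MaSC-enriched replicate 2 the basal call ended (median 0.47, adjusted p = 0.149, with a range over all alternatives of 3.25e-05 to 0.621), and within the beadchips the median was 0.55 and 0.48. The pericyte call ended without control MaSC-enriched replicate 2 (0.09, adjusted p = 0.727), without ovx MaSC-enriched replicate 1 (0.06, adjusted p = 0.411) and without either control luminal sample (0.52, adjusted p = 0.081), with a range over all alternatives of 0.00112 to 0.775 and medians of 0.54 and 0.55 within the beadchips. The pericyte median was 1.03 without control MaSC-enriched replicate 1 and 1.01 without ovx MaSC-enriched replicate 2.

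Proliferation genes (35 tested, covering DNA replication and mitosis) fell in ovx MaSC-enriched cells (median −1.96, adjusted p = 7.84e-07; adjusted p = 0.621 with an estimated correlation). No member passed over all probes or adjusted over the list alone. Mcm6 stood at −2.45, Mcm5 at −2.49 and Cenpa at −2.67, with adjusted p from 0.556 to 0.623. The fall lay in the control replicate 2 pool: the mean log2 level of the list was 10.04 in its MaSC-enriched cells and 7.09 in control MaSC-enriched replicate 1, against 6.91 and 7.18 in the ovx samples. Without control MaSC-enriched replicate 2 the median was −0.05 (adjusted p = 0.767), and without control MaSC-enriched replicate 1 it was −3.58 (5.71e-14, the smallest over all alternatives). Within beadchip 1 it was −1.82, within beadchip 2 −3.33 and with no filter on dim probes −1.02. Immediate early and dissociation stress genes rose (21 tested, median 0.67, adjusted p = 0.00437; 0.621 as the p with an estimated correlation). No member passed, Hspa1b stood at 1.42, and Btg2, not detected on any control MaSC-enriched array, was at least 1.07-fold higher. Their mean level was lowest in the same pool, 12.18 against 13.07 in control MaSC-enriched replicate 1. Without control MaSC-enriched replicate 2 the median was 0.13 (adjusted p = 0.913), and without ovx MaSC-enriched replicate 1 it was 0.62 (adjusted p = 0.0505). It was 1.14 without control MaSC-enriched replicate 1, with 1.07e-05 as the smallest adjusted p over all alternatives and medians of 0.72 and 1.18 within the beadchips. Cholesterol biosynthesis genes fell (17 tested, none past the threshold, median −0.43, adjusted p = 0.0475; 0.628 as the p with an estimated correlation). Without control MaSC-enriched replicate 2 their median was 0.19 (adjusted p = 0.819), without ovx MaSC-enriched replicate 1 −0.19 (adjusted p = 0.301), and without a single luminal sample the adjusted p was 0.126 for the control and 0.0975 for the ovx ones. The median was −1.01 without control MaSC-enriched replicate 1 (adjusted p = 0.000314, the smallest over all alternatives). Within beadchip 1 the cholesterol genes stood at −0.31 (adjusted p = 0.116) and within beadchip 2 at −0.84. Their call also ended with an offset of 50 (−0.26, adjusted p = 0.0882), with the deposited table (−0.27, adjusted p = 0.0907) and without the filter on dim probes (adjusted p = 0.177).

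The remaining 18 lists did not pass in ovx MaSC-enriched cells. The Wnt ligands, receptors and regulators had a median of 0.08 (34 tested, adjusted p = 0.846), with 6 members higher and 2 lower adjusted over the list alone and none over all probes. Sfrp1 stood at 2.58, and Fzd2 was at least 2.04-fold, Wnt11 at least 1.54-fold and Wnt7b at least 3.42-fold higher without passing, with adjusted p from 0.143 to 0.19. Of the Wnt/beta-catenin target genes (12 tested, median −0.46, adjusted p = 0.152), Lgr5, a receptor for R-spondins, stood at 1.73, Axin2 at 0.18, Nkd2 at −2.35 and Lgr6 at −1.98, with adjusted p from 0.221 to 0.963, and 1 member higher and 2 lower passed adjusted over the list alone. The RANK ligand pathway had a median of 0.15 (13 tested, adjusted p = 0.847), with Tnfrsf11a, the gene of the receptor RANK, at 1.59 (adjusted p = 0.635) and Tnfsf11, the gene of its ligand, at least 1.59-fold lower (adjusted p = 0.525). Over all alternatives Tnfrsf11a ranged from 0.50 to 2.67. The oestrogen and progesterone target genes had a median of −0.26 (15 tested, adjusted p = 0.152), with Fkbp5 at −1.93 and Wnt4 at least 1.27-fold higher. Hormone receptors and hormone-sensing luminal markers had a median of 0.42 (adjusted p = 0.495), Notch pathway 0.49 (0.0994), EGF family −0.16 (0.358), CDK inhibitors 0.14 (0.846) and fatty acid synthesis −0.38 (0.0906), with the adjusted p in brackets. Given in the same way, the medians were 0.03 (0.717) for interferon response, and for extracellular matrix −0.06 (0.22), luminal markers 0.20 (0.717), and luminal progenitor markers −0.62 (0.0906). Fibroblast markers had a median of −0.17 (0.719, 1 higher adjusted over the list alone), endothelial 0.64 (0.0906), immune cell 0.74 (0.0906), red blood cell 1.17 (0.0906) and Schwann cell markers −0.45 (0.358). The means of the CDK inhibitor (−0.01) and interferon (−0.04) lists differed in sign from their medians, and the camera test of the RANK ligand pathway pointed down. The keratins Krt5 (0.68), Krt14 (−0.13), Krt8 (0.57) and Krt18 (0.91) and the hormone receptors Pgr (−0.07) and Esr1 (1.34, with a second probe at −1.11) did not pass, and Areg and Mki67 had no tested probe. Pgr turned to 0.18 without ovx MaSC-enriched replicate 1 and 0.15 without control MaSC-enriched replicate 2, Axin2 to −0.05 and −0.06 without the same samples, and Krt14 to 0.05 without control MaSC-enriched replicate 1 and 0.07 without ovx MaSC-enriched replicate 2.

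In luminal cells, where the hormone receptor-positive cells lie, the same comparison asks what loss of the ovaries changed in the fraction that senses ovarian hormones. Tnfsf11, which encodes RANK ligand, a progesterone-induced signal to neighbouring cells, fell by 4.89 on the log2 scale (SE 0.334, adjusted p = 0.0112; at least 28.5-fold), from a mean log2 level of 10.75 ± 0.484 (SD, n = 2) to 5.86 ± 0.0692 (SD, n = 2). The orphan nuclear receptor gene Esrrb fell by 5.63 (SE 0.371, adjusted p = 0.0112, at least 43.3-fold), and Csn2 fell by 6.24 (SE 0.641, adjusted p = 0.0373, 75.4-fold). With single samples left out the Csn2 change ranged from −7.31 to −5.16, so its fold is a rough value. Gjb6, the gap junction protein connexin 30 gene, was at least 22.7-fold lower. Saa1 (at least 25.5-fold, with another probe at −0.84), the growth factor gene Bmp3 (at least 21.6-fold), Bcl2l15 (−4.34), the serotonin synthesis gene Tph1 (−4.27) and the angiotensin receptor gene Agtr1a (−3.43) fell as well, with adjusted p from 0.0373 to 0.0482. Bdnf was at least 11.9-fold lower by its brightest probe (adjusted p = 0.0456), while its 3 other probes lay between −0.15 and −0.94 and did not pass.

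Genes that rose in ovx luminal cells included the complement protease gene Masp1 (4.28, SE 0.517, adjusted p = 0.0482), Aldh3a1 (3.77), the diacylglycerol kinase gene Dgkk (at least 10.1-fold), Brinp1 (at least 4.86-fold) and the prostaglandin receptor gene Ptger3 (at least 2.77-fold). Others were genes of skeletal muscle fibres: creatine kinase Ckm (at least 9.59-fold), phosphoglycerate mutase Pgam2 (at least 8.94-fold), the ribosomal protein gene Rpl3l (at least 5.65-fold) and the fast myosin Myh4 (at least 3.44-fold), with adjusted p from 0.0378 to 0.0482. The surface receptor gene Cd44 stood at 2.22 by its brightest probe (adjusted p = 0.0658) and passed by another (2.74, adjusted p = 0.0378).

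In the luminal comparison 33 of 20995 probes passed in limma, 14 higher and 19 lower in ovx cells, standing for 11 and 13 genes with 8 probes that carry no gene symbol, and 1511 had an unadjusted p under 0.05. Without the muscle genes, left out after the data were seen, 28 passed, 9 higher and 19 lower. With the beadchip as a block 137 passed, and within beadchip 1 none and within beadchip 2 1 passed. None passed without ovx luminal replicate 1 or without either ovx MaSC-enriched sample, 1 without ovx luminal replicate 2, 4 without control luminal replicate 2, 13 without control luminal replicate 1, and 82 without either control MaSC-enriched sample. Without both samples of the control replicate 2 pool 33 passed, 3 higher and 30 lower, of which 13 were the same probes. All 19 genes named as risen or fallen, Tnfsf11, Esrrb and Csn2 among them, lost their calls without ovx luminal replicate 1, either ovx MaSC-enriched sample or control luminal replicate 2. Without ovx luminal replicate 2 all but Csn2 did, and without control luminal replicate 1 all but Esrrb, Tnfsf11 and Bcl2l15.

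Milk protein and secretory genes also fell in luminal cells (16 tested, median −1.17, adjusted p = 4.6e-05; adjusted p = 0.756 with an estimated correlation). Csn2 was the member past the threshold over all probes, and 7 passed adjusted over the list alone, all lower. Wap stood at −4.37 (adjusted p = 0.0639), Cel at −2.36 (adjusted p = 0.42), and Glycam1 was at least 34.7-fold lower without passing (adjusted p = 0.419). Fatty acid synthesis genes fell (14 tested, median −0.52, adjusted p = 4.78e-05; 0.588 as the p with an estimated correlation), with none past the threshold over all probes and 1 adjusted over the list alone, and Thrsp, a regulator of lipid synthesis, at least 9.3-fold lower without passing (adjusted p = 0.132). Both calls held without each library in turn and within beadchip 2 (milk −1.25, fatty acid synthesis −0.57). Within beadchip 1, where 1 luminal sample stands against 1, the medians were −0.89 and −0.32, which tests neither call. Without ovx luminal replicate 1 the fatty acid synthesis median was −0.82.

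Proliferation genes fell in luminal cells (35 tested, median −2.08, adjusted p = 6.32e-11; adjusted p = 0.82 with an estimated correlation), with no member past the threshold, Birc5 at least 12.1-fold and Mybl2 at least 4.91-fold lower (another Mybl2 probe at 0.09). Their mean log2 level was 10.36 in control luminal replicate 2 and 7.69 in replicate 1, against 6.82 and 7.05 in the ovx samples. Without control luminal replicate 2 the list's median was −0.64, still past the threshold, and without control luminal replicate 1 it was −3.49. Within beadchip 1, which holds replicate 1 of both groups, it was −0.69, against −2.10 within beadchip 2. Immediate early genes rose (21 tested, none past the threshold, median 0.63, adjusted p = 0.0166; 0.82 as the p with an estimated correlation), with Jun at 1.58. That call ended without control luminal replicate 2 (median 0.16), without ovx luminal replicate 1 (0.38) and without either ovx MaSC-enriched sample. Within beadchip 1, where 1 luminal sample stands against 1, the median was 0.23, which does not test the call. Within beadchip 2 the median was 0.65, and the smallest adjusted p over all alternatives was 0.00959. The immediate early call ended without the filter on dim probes too (0.61, adjusted p = 0.0605), and without control luminal replicate 1 the median was 1.11. Endothelial markers rose (11 tested, none past the threshold, median 0.67, adjusted p = 0.00994; 0.82 as the p with an estimated correlation), with Eng at 2.10 and Cldn5 at 1.20. Their call ended without control luminal replicate 1 (0.53, adjusted p = 0.21), without ovx luminal replicate 2 (0.42, adjusted p = 0.0802) and without the filter on dim probes (0.63, adjusted p = 0.0664). Over all alternatives the adjusted p ranged from 0.00177 to 0.82, and within beadchips 1 and 2 the median was 0.56 and 0.66.

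**Figure D2:**
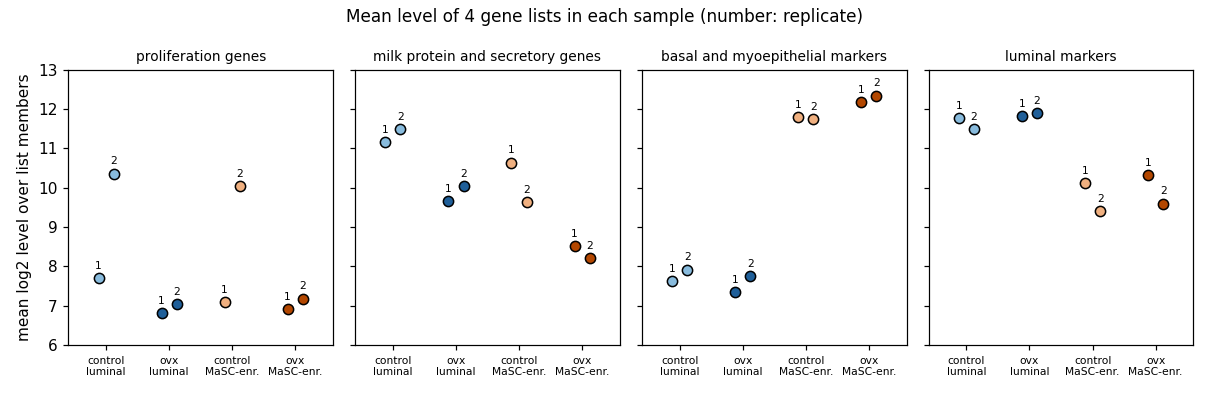
Mean log2 level over the tested members of 4 gene lists (vertical axis) in each of the 8 samples, grouped by fraction and treatment (horizontal axis) and marked with the replicate number. Both samples of the control replicate 2 pool have high proliferation genes (10.36 and 10.04), milk genes are lower in ovx than in control samples of the same fraction, and basal markers are high in the MaSC-enriched samples.

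The other 20 lists did not pass in luminal cells. The oestrogen and progesterone target genes had a median of −0.19 (15 tested, adjusted p = 0.0981), with Tnfsf11 past the threshold, 2 lower adjusted over the list alone, Fkbp5 at −2.39 (adjusted p = 0.157), Pgr, the progesterone receptor gene, at −2.04 (adjusted p = 0.454) and Wnt4 at 0.13. Hormone receptors and hormone-sensing luminal markers had a median of 0.35 (9 tested, adjusted p = 0.925), with Esrrb past the threshold and Esr1, the oestrogen receptor gene, at 2.00 (adjusted p = 0.322). Their mean (−0.26) and test pointed the other way, and 1 member higher and 2 lower passed adjusted over the list alone. The RANK ligand pathway had a median of 0.03 (adjusted p = 0.935) and a mean of −0.23, with Tnfsf11 past the threshold and Tnfrsf11a at −0.27. Wnt ligands, receptors and regulators had a median of 0.17 (adjusted p = 0.722), Wnt/beta-catenin target genes 0.10 (0.863, mean −0.08), Notch pathway 0.56 (0.115, with Hey2 at least 2.99-fold higher), EGF family 0.12 (0.586), and CDK inhibitors 0.10 (0.722, with Cdkn1a at 1.28), with the adjusted p in brackets. Given in the same way, the medians were −0.41 (0.0604) for cholesterol biosynthesis, and for interferon response −0.04 (0.863, mean 0.07), extracellular matrix 0.16 (0.841), luminal markers 0.16 (0.52), luminal progenitor markers −0.08 (0.925, mean 0.05), and basal and myoepithelial markers −0.18 (0.28). Fibroblast markers had a median of −0.89 (0.0529), adipocyte 0.09 (0.496, with Car3 at least 3.4-fold higher), pericyte 0.30 (0.284, with Des at 2.07), immune cell −0.07 (0.586), red blood cell 0.20 (0.496) and Schwann cell 0.07 (0.984). Adjusted over the list alone, 1 member higher passed in the Wnt/beta-catenin target, Notch, EGF family, adipocyte, pericyte and red blood cell lists, and 1 higher and 2 lower in the basal list. The tests of the luminal progenitor and Schwann cell lists pointed down. The keratins Krt5 (−0.44), Krt14 (−2.18), Krt8 (0.14) and Krt18 (0.09) and Axin2 (at least 1.95-fold lower) did not pass. Without control luminal replicate 2, Krt5 turned to 0.14, Wnt4 to −0.13 and Tnfrsf11a to 0.14; Krt5 also turned without ovx luminal replicate 1 (0.08), Krt8 without control luminal replicate 1 (−0.08) and Krt18 without ovx luminal replicate 2 (−0.04).

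Whether ovariectomy acted differently in the fractions was tested directly as the difference of the effects (MaSC-enriched minus luminal). No probe passed in limma, with a smallest adjusted p of 0.0557 and 952 probes with an unadjusted p under 0.05. Esrrb (4.64, SE 0.525) and Tnfsf11 (4.03, SE 0.472) had positive differences, being high in control luminal cells alone, at adjusted p = 0.113. Lep stood at 4.77 (adjusted p = 0.165), Cd44 at −2.98 (adjusted p = 0.221), Fzd2 at 2.28 (adjusted p = 0.453), Csn1s1 at −2.33 (adjusted p = 0.662) and Csn2 at −2.22 (adjusted p = 1). For Esrrb, Tnfsf11, Lep, Fzd2 and Csn2 some arrays lay below the detection floor, so the sizes of these differences depend on the offset. The beadchip block gave 9 probes, and none passed within either beadchip. Of the 25 lists, the basal and myoepithelial markers passed (24 tested, none past the threshold, median 0.87, adjusted p = 0.000622; adjusted p = 0.914 with an estimated correlation). Among them were Cnn1 at 1.92 and Tcf7l1 at 2.34. Their median was 0.49 in MaSC-enriched and −0.18 in luminal cells, and 1.04 and 0.91 within beadchips 1 and 2. Without control MaSC-enriched replicate 2 it was 0.79 (adjusted p = 0.0658, with a range over all alternatives of 1.75e-08 to 0.914), and without ovx luminal replicate 1 it was 0.57 (adjusted p = 0.0143). The other 24 lists had adjusted p from 0.119 to 0.917, with proliferation genes at 0.64 and milk genes at −0.25. Median and mean differed in sign for the Wnt ligand (−0.11 and 0.02), Notch (0.0078 and −0.03) and cholesterol (−0.04 and 0.05) lists.

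Across probes the effects of ovariectomy in the fractions had a Pearson r of 0.422 and a Spearman rho of 0.394, with the same sign for 64.6% of probes. The value was 0.414 with MaSC-enriched cells from beadchip 1 and luminal cells from beadchip 2. Probes are not independent replicates, and the mouse pools are shared between the 2 effects: the deviations of replicates from their group means correlated at 0.367 between the fractions of the control pools and at 0.135 between those of the ovx pools. The other 2 splits of the 4 pools into 2 and 2, each with a control and an ovx pool on both sides, gave r of 0.332 and 0.273, so pools that do not differ in treatment as a whole gave positive values too, and 3 splits are too few for a test of 0.422. Called in both fractions were Brinp1 as higher and Csn2 with 1 probe lacking a symbol as lower, and no test of this overlap was made that keeps the shared pools.

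The comparison of MaSC-enriched with luminal cells in control mice describes the sorted fractions themselves. Of the basal and myoepithelial markers, 21 of 24 passed, all higher in MaSC-enriched cells (median 4.35, adjusted p = 2.68e-23; adjusted p = 0.111 with an estimated correlation), and 24 passed adjusted over the list alone. They included the basal transcription factor gene Trp63 (6.60, SE 0.45, adjusted p = 0.000579), smooth muscle actin Actg2 (6.52, SE 0.412, adjusted p = 0.000459), smooth muscle myosin Myh11 (6.16), Tagln (at least 47.6-fold), Tpm2 (5.41, with 2 other probes near 1, at 1.08 and 1.01) and Snai2 (at least 49.3-fold). The basal keratins Krt5 (at least 69.5-fold, adjusted p = 0.00125) and Krt14 (2.37, adjusted p = 0.0432) were higher as well, and the Krt14 call ended without either control luminal sample, control MaSC-enriched replicate 1 or either ovx MaSC-enriched sample. Among the largest rises were also Tenm2 (at least 110-fold), the hemidesmosome collagen Col17a1 (6.49) and Reln (6.45). Extracellular matrix and basement membrane genes were higher (15 of 23 passed, 17 over the list alone, median 2.46, adjusted p = 3.44e-12; 0.111 as the p with an estimated correlation), among them Col7a1 (6.40) and the laminin gene Lama1 (5.36).

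Hormone receptors and hormone-sensing luminal markers were lower in control MaSC-enriched cells (6 of 9 passed, 9 over the list alone, median −3.16, adjusted p = 8.85e-06; 0.275 as the p with an estimated correlation). They included Esrrb (at least 23.3-fold, adjusted p = 0.000592), Cited1 (at least 26.6-fold), Foxa1 (−4.68), Pgr (at least 4.41-fold, adjusted p = 0.0216) and Esr1 (−2.64, adjusted p = 0.0209, with a second probe at 0.60). Without control luminal replicate 1 the calls of Cited1, Foxa1, Pgr and Esr1 ended, as did that of Pgr without control MaSC-enriched replicate 1 and that of Esr1 without either ovx luminal sample. Tnfsf11 (at least 13.7-fold, adjusted p = 0.000956), Wnt4 (at least 15.5-fold), Tph1 (at least 19.8-fold), the tight junction gene Cldn6 (at least 21.6-fold) and Bmp3 (at least 14.6-fold) were lower too. Luminal markers were lower (5 of 16 passed, 14 over the list alone, median −2.00, adjusted p = 3.43e-06; 0.275 as the p with an estimated correlation), with Krt18 at −2.31 (adjusted p = 0.0652) and Krt8 at −0.75 (adjusted p = 0.21). Of the luminal progenitor markers (median −1.68, adjusted p = 0.0702), Aldh1a3 passed (at least 4.5-fold lower, adjusted p = 0.0413; another probe at −1.66, adjusted p = 0.0548) and Kit passed by another probe only (−2.68, adjusted p = 0.0039). The Aldh1a3 call ended without any luminal sample or control MaSC-enriched replicate 1. Milk protein and secretory genes were lower (2 of 16 passed, 3 over the list alone, median −1.39, adjusted p = 0.0192; 0.585 as the p with an estimated correlation), with Wap at −2.61 (adjusted p = 0.0393), whose call ended without any sample but control luminal replicate 1 and control MaSC-enriched replicate 2. The milk call ended without control MaSC-enriched replicate 2 (−0.44, adjusted p = 0.708), without control luminal replicate 2 (−0.96, adjusted p = 0.131), without either ovx MaSC-enriched sample (−1.39, adjusted p = 0.0557) and within beadchip 1 (−1.07, adjusted p = 0.0799), with 0.000107 as the smallest over all alternatives and −1.60 as the median within beadchip 2.

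Signalling genes also parted the fractions in control mice. Lgr5, Jag2 and Tcf7l1 are on the basal marker list as well, so the signalling lists are not fully separate from it. Wnt ligands, receptors and regulators were higher in MaSC-enriched cells (8 higher and 2 lower of 34, 12 and 4 over the list alone, median 0.51, adjusted p = 0.00176; 0.137 as the p with an estimated correlation). The secreted Wnt inhibitor Wif1 stood at 5.89, Dkk3 at 4.96 and Wnt10a was at least 37.5-fold higher. Wnt/beta-catenin target genes were higher (4 of 12, 6 over the list alone, median 1.47, adjusted p = 0.00095; 0.275 as the p with an estimated correlation). Of these Lgr5 was at least 9.97-fold and Nkd1 at least 14.7-fold higher (another Nkd1 probe at −0.39). Notch pathway genes were higher (2 of 17, 6 over the list alone, median 0.36, adjusted p = 0.0341; 0.275 as the p with an estimated correlation). The ligand gene Dll1 stood at 5.58, and Jag2 was at least 18.4-fold higher. Their call ended within beadchip 1 (0.41, adjusted p = 0.0756), with a range over all alternatives of 0.000529 to 0.275 and of −0.02, without control MaSC-enriched replicate 1, to 0.79, without control MaSC-enriched replicate 2, for the median. It was 0.65 and 0.62 without control luminal replicates 1 and 2, and without the latter the Wnt/beta-catenin target genes stood at 2.21. The Notch median was 0.07 within beadchip 2, and that of the Wnt/beta-catenin target genes 2.23 within beadchip 1. With no filter on dim probes the Wnt ligand list stood at 0.32 and the Wnt/beta-catenin target genes at 0.74. The EGF family ligand gene Nrg1 was at least 30.1-fold higher by its brightest probe, with 2 other probes at 4.59 and 1.27, the latter not past the threshold (adjusted p = 0.254), and the EGF family list did not pass (adjusted p = 0.751). Tnfrsf11b, which encodes the RANK ligand decoy receptor, was at least 15.6-fold higher, a call that ended without either control luminal sample, and Tnfrsf11a stood at 0.83 (adjusted p = 0.51; −0.25 without control MaSC-enriched replicate 1).

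Although CD31-positive cells were depleted in the sort, endothelial markers were higher in control MaSC-enriched than in luminal cells (7 of 11 passed, 11 over the list alone, median 2.26, adjusted p = 1.77e-06; 0.392 as the p with an estimated correlation), with Cldn5 at 3.05 and Emcn at 2.47. Pericyte markers were higher (4 of 9, 7 over the list alone, median 1.99, adjusted p = 0.000357; 0.392 as the p with an estimated correlation), with Des at 2.80 and Rgs5 at 2.72. Fibroblast markers were higher (1 of 16 over all probes and over the list alone, median 0.87, adjusted p = 0.00778; 0.705 as the p with an estimated correlation). The calls of Cldn5, Emcn, Des and Rgs5 ended without either control luminal sample, those of Cldn5, Emcn and Rgs5 also without control MaSC-enriched replicate 1, and those of Emcn and Rgs5 without either ovx luminal sample. The fibroblast call ended without control luminal replicate 1 (0.29, adjusted p = 0.233) and without control MaSC-enriched replicate 2 (0.66, adjusted p = 0.267), with a range over all alternatives of 2.84e-06 to 0.705. The fibroblast median was 1.56 without control MaSC-enriched replicate 1 and 1.81 without control luminal replicate 2. Within beadchips 1 and 2 the medians were 2.46 and 1.75 for endothelial, 1.77 and 1.45 for pericyte, and 1.84 and 1.66 for fibroblast markers. Pericyte markers stood at 1.23 with an offset of 50. In control mice the other 14 lists had adjusted p from 0.0558 to 0.751, and median and mean differed in sign for the EGF family (−0.06 and 0.06) and immediate early (−0.04 and 0.07) lists.

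In limma 2122 probes passed between the fractions in control mice, 1168 higher and 954 lower in MaSC-enriched cells, standing for 826 and 695 genes. The split was 1410 and 726 with 75th percentile scaling, and the median log2 fold change of all probes moved from −0.16 to −0.02. With the mouse pool as a fixed block 2122 passed, 1792 of them the same probes, with the pool as a random block 3177, and with the beadchip as a block 2532. Within beadchip 1 181 passed and within beadchip 2 1725. Left out singly, control luminal replicate 1 gave 656 probes, control luminal replicate 2 1378 and either ovx luminal sample 1104. Control MaSC-enriched replicate 1 gave 1575, either ovx MaSC-enriched sample 1622, and control MaSC-enriched replicate 2 5503.

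**Figure D3:**
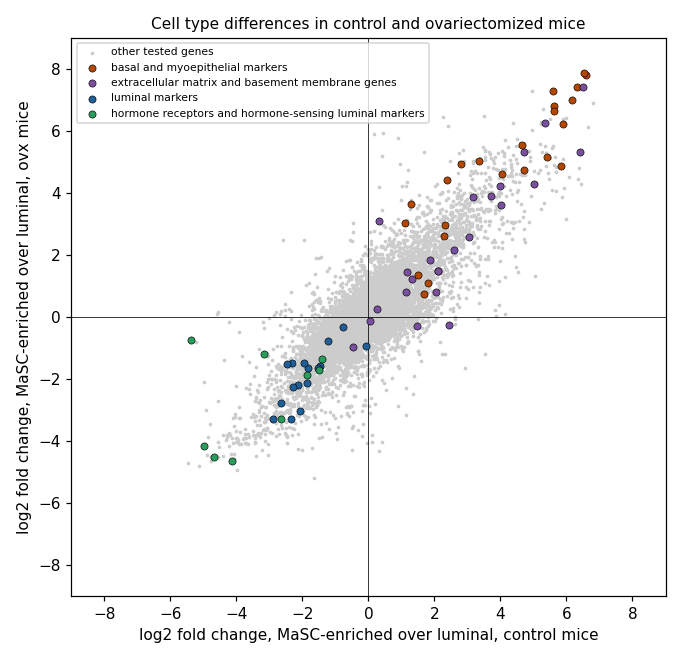
Log2 fold change of MaSC-enriched over luminal cells in control mice (horizontal axis) and in ovx mice (vertical axis), with a point per gene and the members of 4 gene lists in colour. Basal markers such as Actg2 (6.52 and 7.86) lie at the upper right and hormone-sensing luminal markers such as Esr1 (−2.64 and −3.31) at the lower left, while Esrrb (−5.37 in control mice) lies apart from the diagonal.

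In ovx mice 2596 probes passed between the fractions, 1536 higher (1067 genes) and 1060 lower (751 genes) in MaSC-enriched cells. Of these, 1494 passed in control mice too, all in the same direction (914 higher and 580 lower, against 85.5 and 48.2 if independent), and the effects correlated at r = 0.818 across probes. Both comparisons share one estimate of the spread per probe, so the values for independence are a description and no test. Basal markers were again higher (22 of 24 passed over all probes and over the list alone, median 4.89, adjusted p = 2.95e-24; 0.112 as the p with an estimated correlation), with Actg2 at least 185-fold, Krt5 at least 130-fold and Tagln at least 98.6-fold higher and Krt14 at 4.42. Col17a1 was at least 166-fold higher. Axin2, a Wnt/beta-catenin target, was at least 8.1-fold higher (adjusted p = 0.00997), Lgr5 stood at 4.61 (adjusted p = 0.00182) and Lep was at least 26.6-fold higher (adjusted p = 0.00101). Wnt4 (−3.73) and Esr1 (−3.31, with a second probe at −1.14 that did not pass, adjusted p = 0.101) were lower, and so were Csn2 (at least 6.3-fold, adjusted p = 0.028) and Csn1s1 (−2.86, adjusted p = 0.00738). Pgr (at least 1.7-fold lower, adjusted p = 0.28) and Tnfsf11 (−0.18, adjusted p = 0.817) did not pass. The calls of Esr1 and Axin2 ended without either ovx luminal sample or without ovx MaSC-enriched replicate 2, and that of Axin2 without ovx MaSC-enriched replicate 1 too. That of Csn2 ended without either control luminal sample, either ovx MaSC-enriched sample or ovx luminal replicate 2, and that of Csn1s1 without ovx MaSC-enriched replicate 2 or ovx luminal replicate 2.

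The other 11 lists that passed in ovx mice were extracellular matrix genes (13 of 23 higher, median 2.16, adjusted p = 5.4e-09; 0.191 as the p with an estimated correlation) and luminal markers (7 of 16 lower, −1.65, 2.16e-06; 0.383 with it estimated). With values in the same order, they included hormone receptors and hormone-sensing luminal markers (4 of 9 lower, −1.89, 0.00015; 0.383), endothelial (8 of 11 higher, 2.26, 3.26e-05; 0.383), pericyte (6 of 9 higher, 2.13, 0.00015; 0.383) and fibroblast markers (5 of 16 higher, 2.03, 0.00015; 0.464). They also included immune cell markers (1 of 11 higher, 1.42, 0.00141; 0.383), milk protein and secretory genes (4 of 16 lower, −1.64, 0.00193; 0.383), luminal progenitor markers (4 of 9 lower, −1.88, 0.00745; 0.383), Wnt ligands, receptors and regulators (10 higher and 3 lower of 34, 0.33, 0.00825; 0.238) and Wnt/beta-catenin target genes (5 higher and 1 lower of 12, 1.43, 0.0223; 0.383). Adjusted over the list alone the counts were 16, 13, 6, 10, 7 and 7 for the first 6 lists, and 1, 7, 4, 14 and 7 for the others. Among pericyte markers Pdgfrb was at least 7.09-fold and Abcc9 at least 3.57-fold higher, both past the threshold, and both calls ended without either ovx luminal sample or ovx MaSC-enriched replicate 1, that of Pdgfrb also without ovx MaSC-enriched replicate 2. The immune cell call ended without ovx luminal replicate 1 (0.92, adjusted p = 0.0604), without ovx MaSC-enriched replicate 1 (0.88, adjusted p = 0.12) and within beadchip 2 (0.93, adjusted p = 0.114), with a range over all alternatives of 0.00142 to 0.383. Fibroblast markers stood at 0.86 without ovx luminal replicate 1, and the Wnt ligand list at 0.63 without ovx MaSC-enriched replicate 1. With no filter on dim probes the Wnt/beta-catenin target genes stood at 0.21, the Wnt ligand list at 0.15 and immune cell markers at 0.84. With an offset of 50 pericyte markers stood at 1.31 and immune cell markers at 0.88. The other 13 lists had adjusted p from 0.0623 to 0.946, and median and mean differed in sign for the RANK ligand (−0.17 and 0.33) and red blood cell (1.08 and −0.0033) lists. With the mouse pool as a fixed block 2748 probes passed, with the pool as a random block 3632 and with the beadchip as a block 3010, against 262 within beadchip 1 and 2687 within beadchip 2. Left out singly, ovx luminal replicate 1 gave 508 probes, ovx luminal replicate 2 729, ovx MaSC-enriched replicate 2 1022 and ovx MaSC-enriched replicate 1 1301.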

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

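The tests of a single ovx luminal pool, of a beadchip effect, of dim transcripts and of the milk genes below were chosen only after results they measure were seen; the test of further muscle genes was written after the called muscle genes were seen and before the values it measures were.

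The effect of ovariectomy on basal and myoepithelial markers passed a direct test of the difference between the fractions at the preset correlation (24 genes, 18 of them above 0, median 0.87, camera adjusted p = 0.000622, limma fit), but not with an estimated correlation between genes (adjusted p = 0.914). The markers rose in MaSC-enriched cells (median 0.49; adjusted p = 0.621 with an estimated correlation, and no member past the threshold over all probes) and stood at −0.18 in luminal cells. The call also ended with fry (0.476) and without control MaSC-enriched replicate 2 (median 0.79, adjusted p = 0.0658).

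Skeletal muscle genes were higher in ovx than in control luminal cells, with Ckm, Pgam2, Rpl3l and Myh4 past the threshold. RNA of muscle fibres carried into the ovx luminal samples may explain this. Of 17 further muscle genes, listed with the called ones left out, the 14 with a tested probe had a median log2 fold change of 4.03 (95% bootstrap interval over genes 2.62 to 4.34), and all 14 were detected on the 3 ovx luminal arrays, with Pvalb at 4.79, Myl1 at 4.42, Acta1 at 4.39 and Mb at 0.19. Pvalb, Myl1, Acta1 and Mb were detected on the 3 control luminal arrays too, so detection alone does not set the ovx samples apart for these genes. Mybpc2 and Ryr1 were detected on 0 of the control luminal arrays, Tnnt3, Tnnc2 and Cox6a2 on 2, and the other uncalled genes on all 3. Of the called genes, Rpl3l and Myh4 lay below the detection floor on 3 control luminal arrays, and Ckm and Pgam2 on 2. Acta1 had a log2 level of 9.60 in control luminal replicate 1 and 10.25 in control MaSC-enriched replicate 1. In MaSC-enriched cells the ovx effect was 1.26 for Pvalb, 0.09 for Myl1, 0.46 for Acta1 and −0.53 for Mb, none past the threshold. A single ovx luminal pool as the source was excluded, since the 2 ovx luminal samples differed by a median of 0.638 (interval 0.477 to 0.818) over 18 muscle genes. Over the 14 uncalled ones it was 0.694 (0.502 to 0.854), and the lower ovx sample lay above the higher control sample by a median of 3.00 (2.14 to 3.43). No biological explanation was tested.

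Proliferation genes were high in both fractions of the control replicate 2 pool, by a mean of 2.66 over replicate 1 in luminal cells (35 of 35 genes) and 2.95 in MaSC-enriched cells (34 of 35 genes). A beadchip effect of this size was excluded for the MaSC-enriched RNA run on both beadchips, which differed between them by −0.0206 (95% bootstrap interval −0.0807 to 0.044). This interval and the next resample genes as if independent, and do not measure the spread between arrays or pools. Loss of dim transcripts in control MaSC-enriched replicate 1 as the whole cause was excluded by the luminal gap of 2.66 (interval 2.36 to 2.95), where that array plays no part. A difference between the control mice of the pools, for example in the stage of the oestrous cycle, which the labels do not give, may underlie it and was not tested. With 2 control pools the fall of these genes after ovariectomy rests on this pool in MaSC-enriched cells.

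Milk protein genes were high in control MaSC-enriched cells, where Csn2 reached a mean log2 level of 14.08. Luminal cells carried into the sort and expression in the MaSC-enriched cells themselves cannot be told apart by the marker levels. The 6 milk genes lay a median of −0.981 from their luminal level and 23 luminal and luminal progenitor markers lay −1.94 from theirs, a gap of 0.961 with a 95% bootstrap interval over genes of −0.791 to 1.61 that spans 0, and the small number of milk genes keeps this open.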

How the results depend on the processing

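The omission of the control replicate 2 pool, the other splits of the pools, the list tests within each beadchip and the count without muscle genes were tests chosen only after results were seen. With 2 samples per group, leaving 1 out leaves a lone sample that is assumed to vary like the other groups. Without control MaSC-enriched replicate 2 the lone sample is replicate 1, the array with 12994 detected probes and a detection floor of 7.29. The larger counts without it, in the ovx comparison of MaSC-enriched cells and the cell type comparison in control mice, take their control MaSC-enriched level from that array. The ovx comparison in luminal cells and the cell type comparison in ovx mice use no control MaSC-enriched sample. Their counts rose too when either control MaSC-enriched sample was left out, which changed only the shared estimate of the spread. The cause of the changes below was not tested. The fit of the contrast's groups alone could not be run for the difference of effects, which uses all 4 groups. The ovx comparisons share no pool between control and ovx samples, so their replicate block joins samples by number alone.

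Of the alternatives for 152 gene results, 3203 kept direction and side of the threshold, 427 lost the call, 68 gained it and 25 turned direction. Many of these results were not past the threshold and could not lose a call, so the totals do not show how stable the calls are. Among called genes, Rpl3l in ovx luminal cells lost its call in 18 of 25 alternatives, and Trim9 in ovx MaSC-enriched cells in 4 of 25. Over all alternatives the smallest fitted log2 change was 3.57 for Trim9 and −6.71 for Csn2 in ovx MaSC-enriched cells. In ovx luminal cells it was −4.00 for Esrrb and −3.37 for Tnfsf11. These are smaller in size than the bounds of the main fit, 4.24, 8.21, 5.44 and 4.83 on the log2 scale. For 36 gene list results 521 kept direction and side of the threshold, 101 lost the call and 2 turned, with the direction taken from the list test and not from the median. The Notch median in control mice, 0.36, reached −0.02 without control MaSC-enriched replicate 1, and this is not counted as a turn. For 11 counts and correlations 121 stayed within 1.5 times or the spread and 92 moved further.

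For ovx MaSC-enriched cells 16 probes became 5 with 75th percentile scaling, 26 without a filter, 26 with the strict filter and 115 with the RNA as a random block. It became 81 with the beadchip as a block (all 16 kept), 0 within beadchip 1, 0 within beadchip 2, 5 with array weights, 0 with the groups of the contrast alone, 36 with the replicate block and 410 without the control replicate 2 pool. Leaving out single samples gave 0 (ovx MaSC-enriched replicate 2) to 583 (control MaSC-enriched replicate 2).

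For ovx luminal cells 33 probes became 55 with 75th percentile scaling, 170 with the RNA as a random block, 137 with the beadchip as a block, 0 within beadchip 1 and 1 within beadchip 2. They became 57 with a mean-variance trend, 231 with array weights, 3 with the groups of the contrast alone and 52 with the replicate block. Leaving out single samples gave 0 (ovx luminal replicate 1 or either ovx MaSC-enriched sample) to 82 (either control MaSC-enriched sample).

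For the difference of effects 0 probes became 2 with an offset of 50, 4 without background correction, 2 with the deposited normalized table, 1 without a filter and 2 with the strict filter. They became 27 with the RNA as a random block, 9 with the beadchip as a block, 2 with array weights and 2 with the mouse pool as a random block. With 952 probes at an unadjusted p under 0.05 in limma, it stayed 0 without each single sample.

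For cell type in control mice 2122 probes became 181 within beadchip 1 (169 of them the same), 854 with array weights and 475 with the groups of the contrast alone. They became 656 (without control luminal replicate 1) to 5503 (without control MaSC-enriched replicate 2) when single samples were left out. For cell type in ovx mice 2596 became 262 within beadchip 1 (261 the same), 4909 with array weights and 4337 with the groups of the contrast alone. They became 508 (without ovx luminal replicate 1) to 3779 (without either control MaSC-enriched sample).

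Of the list calls, 7 in ovx MaSC-enriched cells became 0 with an estimated correlation, 0 with fry, 4 without the control replicate 2 pool and 4 to 10 without single samples. The 5 in ovx luminal cells became 0 with an estimated correlation, 0 with fry, 9 with the replicate block, 8 within beadchip 1, 9 within beadchip 2 and 5 to 8 without single samples. The 1 in the difference became 0 with an estimated correlation, 0 with fry, 2 with an offset of 50 and 3 with the deposited table. It became 2 with the beadchip block, 5 with the mouse pool as a fixed block, 6 within beadchip 1, 4 within beadchip 2 and 2 to 6 without single samples. The 11 in control mice became 0 with an estimated correlation and 7 with fry, and the 12 in ovx mice 0 with an estimated correlation. The correlation of effects, 0.422, was 0.447 with an offset of 50, 0.381 without a filter and 0.434 with the deposited table.

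Cholesterol genes in ovx MaSC-enriched cells turned to 0.19 without the control replicate 2 pool and ranged from −1.01 to 0.19 without single samples. In the same comparison Pgr turned to 0.13 within beadchip 2 and 0.15 without that pool (−0.33 to 0.18 without single samples), and Axin2 to −0.060 without that pool (−0.060 to 0.42). Krt14 ranged from −0.34 to 0.071. In ovx luminal cells Tnfrsf11a turned to 0.14 without that pool (−0.68 to 0.14), Wnt4 to −0.21 within beadchip 1 and −0.13 without that pool (−0.13 to 0.38), Krt5 to 0.14 without that pool (−1.02 to 0.14). Krt18 turned to −0.0046 with the first arrays and −0.30 within beadchip 1 (−0.038 to 0.22), and Krt8 ranged from −0.081 to 0.36. Between cell types Tnfrsf11a in control mice turned to −0.019 within beadchip 2 (−0.25 to 1.92 without single samples), and Tnfsf11 in ovx mice to 0.036 with 75th percentile scaling and 0.00092 within beadchip 1. None of these genes was past the threshold in the comparison named.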

Other observations

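The contrasts of Esrrb and Tnfsf11 were noted only after the tables were read, and no tests of an explanation were made for them. In control mice both genes were far lower in MaSC-enriched than in luminal cells (Esrrb at least 23.3-fold, Tnfsf11 at least 13.7-fold), and in ovx luminal cells both fell, by 5.63 and 4.89 on the log2 scale. Bmp3 and Tph1 were also lower in control MaSC-enriched cells (Tph1 at least 19.8-fold, Bmp3 at least 14.6-fold) and lower in ovx than in control luminal cells (Tph1 −4.27, Bmp3 at least 21.6-fold). Both comparisons use the same 2 control luminal samples, so a high level in these gives both falls, and no value for this by chance was worked out. Foxa1 and Esr1, which mark the hormone-sensing cells, were not among the genes that fell in ovx luminal cells. There Esr1 stood at 2.00 (adjusted p = 0.322 in limma, with a second probe at 0.63 and adjusted p = 0.809) and Foxa1 at 0.34 (adjusted p = 0.96). Pgr, on the same list of hormone-sensing markers, stood at −2.04 (adjusted p = 0.454 in limma). The list did not pass, with a median of 0.35 and a mean of −0.26, so its members do not point one way.

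Lep, the leptin gene, was at least 15.7-fold higher in ovx than in control MaSC-enriched cells and at least 26.6-fold higher in ovx MaSC-enriched than in ovx luminal cells. The adipocyte markers Adipoq (at least 1.75-fold) and Car3 (at least 1.63-fold) did not pass in the former comparison, and no source of the leptin transcript was tested. Over all alternatives the fitted log2 change ranged from 0.60 to 1.96 for Adipoq and from 0.695 to 1.66 for Car3. For Lep it ranged from 3.21 to 5.60 in ovx against control MaSC-enriched cells. Between the fractions in ovx mice Lep ranged from 3.38 to 5.95. The bounds of Lep, Adipoq and Car3 therefore hold for the main fit only.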
